A study of Homo sapiens with 2 samples.

How the data were processed

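Total RNA from 2 SAS cultures, 1 per group, was compared on single-dye (Cy3) Agilent expression arrays. Groups were taken from the submitters' labels, which name the shSNAI1 cells Snail-depleted and the pLKO cells the empty-vector control. Both had been cultured on thick collagen for 24 h, per the labels. The hairpin sequence is not given in the sources used here.

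The intensity values came from the scanner output of each array as deposited by the authors. Agilent Feature Extraction 10.5.1.1 made them, per the file headers, while the submitters' processing notes name version 9.1. The processed signal is a spot's brightness on a linear scale after background subtraction and detrending, per the file headers, and it had not been scaled between arrays. Both arrays lay on the same slide and carried the same scan time and software version, per the file headers, so neither separates the groups. Of 62976 spots per array, 58717 were not controls, and these made 50599 probes, 49697 with 1 spot and 902 with 10 spots.

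The authors' value table was set against the scanner files. Each value of a probe with 1 spot equalled the processed signal within 0.001 log2, and each value of a probe with 10 spots equalled the geometric mean of its spots that were not outliers within 0.01 log2. The table is therefore linear, not centred and not scaled, with medians of 156 for shSNAI1 and 180 for control, and using it in place of the scanner files moves nothing by construction.

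The processed signal was put on the log2 scale, spots of a probe were averaged without outlier spots (228 and 270 spots), and each array's 75th percentile over all non-control probes (852 for shSNAI1, 910 for control) was subtracted. Negative control spots had a median processed signal of 3.68 and 4.44. A probe entered when it was well above background on both arrays and neither an outlier nor saturated; no spot was saturated. Probes of chromosome Y and of 1 X-linked noncoding RNA, 226 in all, were left out. Of the remaining 50373 probes, 31282 were named through the RefSeq gene table of GRCh38.p14, used for names only (28052 by accession, 2612 by symbol, 618 by synonym), and 19091 stayed unnamed. Probe positions are those of the files, in hg19. A gene took the value of its brightest eligible probe. Of 6000 genes with 2 or more eligible probes, 204 were at or beyond 2-fold, and 72.5% of these had all probes on the same side of 0, against 56.4% of the other genes.

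The comparison was the log2 difference, shSNAI1 minus pLKO control, with a size rule of 2-fold. With 1 array per group there is no test and no p-value. The technical error of a difference came from the scanner's error model (median 0.20 log2). The number of arrays limits the precision. A gene well above background on 1 array only was given a bound, its scaled signal over the higher of the lowest signal among probes well above background and its own signal on the dim array. Spots of the same probe had a median SD of 0.14 log2 on the shSNAI1 array and 0.13 on the control array.

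Before the data were examined, 24 gene lists, the 2-fold rule, 9 processing alternatives and the rule for named genes were fixed. The rule took SNAI1 and CLDN11, the 12 highest and 12 lowest genes with the same sign under each background and scaling alternative, the 4 largest bounds per direction, and up to 2 highest and 2 lowest members of each list. Each list's median was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these 2 arrays. Counts of 2-fold members were also set against such random lists, which was not part of what was fixed beforehand. List members outside that rule (such as IL6, IL11, IL1A, IL1B, CXCL3, IFIT2, MX1, MVD and HMGCS1) and the genes on 10 spots or several probes were chosen after their values were seen. Of the lists 1, and of the genes a few, are not reported here. The 9 alternatives were normexp background correction (offset 50) on mean and local background signals, scaling on the median or on the 75th percentile of detected probes, quantile and cyclic loess normalization, no filter, a stricter filter (processed signal of at least 100 on both arrays), the mean of a gene's probes, and the authors' table.

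Neighbouring genes were searched for shared shifts by the median of windows of 25 genes in order of their hg19 position, against the most extreme windows in 1000 shuffles. Genes, lists and windows were tested on simulated data made from the real signals and the noise of replicate spots. Among 19460 genes, the 2-fold rule recovered 65 of 67 genes simulated at 3-fold (97.0%) and 66 of 66 at 6-fold (100%). It passed 1 of 67 at 1.5-fold (1.49%) and 134 of 19260 without a difference (0.696%). A simulated shift of 100 neighbouring genes, larger than the median shift of the real stretches (0.39 log2), was recovered over 100 genes, with 0 other stretches. Only spot noise stood behind it. Recovery therefore does not show how the search behaves at the wider spread of the real differences (SD 0.46 log2). R 4.3.3 with limma 3.58.1 read and normalized the arrays, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 did the rest.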

Results

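Gene expression was measured in SAS, an established human squamous carcinoma line of the tongue, after silencing of SNAI1. SNAI1 encodes Snail, a zinc-finger repressor best known for driving epithelial-mesenchymal transition. The cells grew for 24 h on a thick collagen layer (1.7 mg/mL), a setting in which cancer cells can move as connected groups. The shSNAI1 group, carrying a short hairpin RNA against SNAI1, held 1 array, and the control group, carrying the empty pLKO vector, held 1 array. Total RNA of each culture was labelled with a single dye and hybridised to an expression array with 50599 probes. On the shSNAI1 array 86.1% of probes were well above background, and on the control array 85.6% were. Of 21277 named genes with a probe, 19460 were measured on both arrays. With 1 array per group no test was possible and no difference has a replicate check, so all differences below are descriptions of these 2 arrays.

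The question was which genes differ when Snail is depleted. SNAI1 itself was 2.13-fold lower on the shSNAI1 array, with a processed signal of 520 against 1181 in the control. CLDN11, which encodes the tight-junction protein claudin-11, was 5.47-fold lower, with 510 against 2980. No other claudin or EMT transcription factor reached 2-fold. The cytokine IL24 was 9.58-fold higher, and the mesenchymal cadherins CDH11 (2.76 on the log2 scale) and CDH2 (1.58) were higher too. E-cadherin (CDH1), a textbook target of repression by Snail, was 1.69-fold lower. CDH1 lies in a stretch of chromosome 16 where neighbouring genes were lower together, 44 of 50 of them below 0. The median of that stretch was -0.43 on the log2 scale, against -0.76 for CDH1. The lower CDH1 value therefore cannot be read as a difference of this gene alone.

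The SNAI1 difference was -1.09 on the log2 scale, with a technical error of 0.20 from the scanner's error model, and CLDN11 stood at -2.45 with the same technical error of 0.20. Each gene had 1 probe with 1 spot, at hg19 chromosome 20, 48605170 to 48605229 for SNAI1 and chromosome 3, 170151824 to 170151883 for CLDN11. The mean signal of SNAI1 lay between 512 and 1000, where 3.59% of genes on 1 spot were at least 2-fold apart. Single spots of 10-spot probes deviated at least 2-fold from their probe's mean difference in 0.69% of cases there. The technical error is computed by the scanner's model, and its median over all genes was 0.20 as well. It is not a spread measured between replicate spots, and it does not cover differences between cultures.

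At or beyond 2-fold, 327 genes were higher and 402 were lower in the shSNAI1 cells, 3.75% of the genes measured on both arrays, and 47 and 63 of them were at or beyond 4-fold. Log2 values of the arrays correlated across genes with r = 0.988, where genes are not independent replicates. Scaling on each array's median moved the median of all genes by 0.11, and the split to 452 higher and 318 lower (58.7% of the calls higher, against 44.9%). Dim genes weighed heavily in these counts: among the 8725 genes with a mean signal of 1000 or more, 113 were higher and 74 lower.

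**Figure D1:**
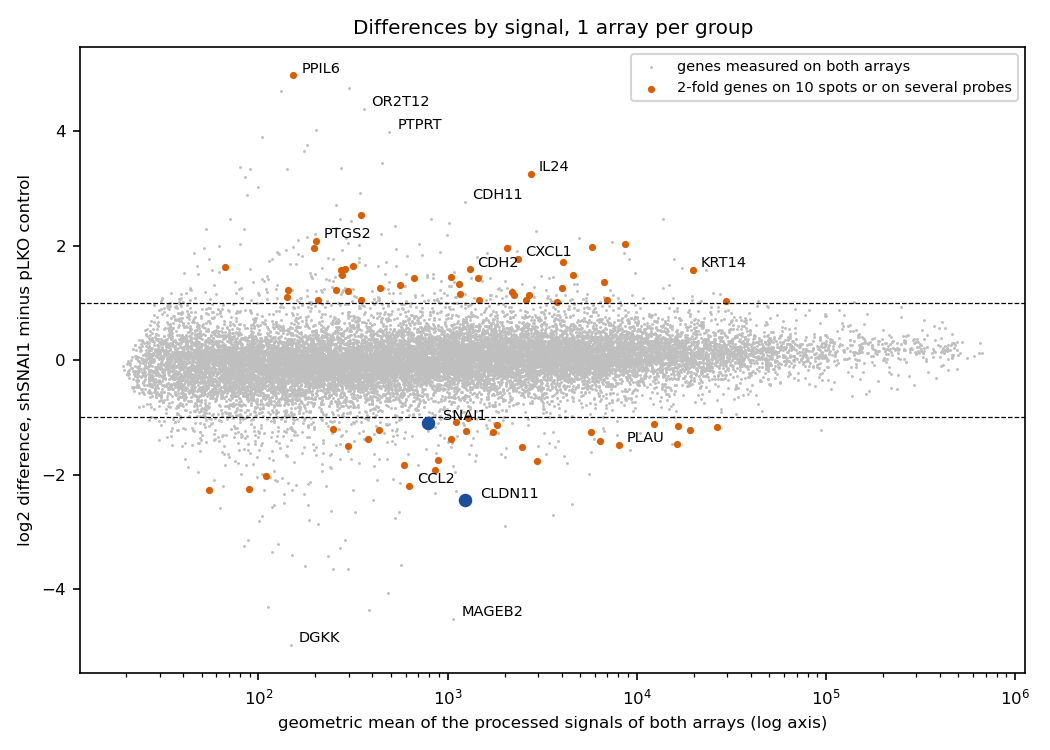
Log2 difference of each gene (shSNAI1 minus pLKO control, vertical axis) against the geometric mean of its processed signals on both arrays (log axis). Each point is 1 gene on 1 array per group, orange points are 2-fold genes that rest on 10 spots or on several probes, blue points are SNAI1 (-1.09) and CLDN11 (-2.45), and dashed lines mark the 2-fold rule.

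Genes that rest on 10 spots, or on several probes that were all at least 2-fold apart in 1 direction, give the firmest differences, and were singled out after their values were seen. There were 41 such genes higher and 27 lower. Among them, ROR1 and FRY had 10 spots but other probes as low as -0.14 and 0.23, and the 2 probes of PPIL6 stood at 1.09 and 4.97. Besides IL24 (3.26 and 3.52 log2 by its 2 probes), the higher genes included the phosphatase PTPRR (2.53), the prostaglandin synthase PTGS2 (2.09), the myosin regulator LIMCH1 (1.98), the phosphatase DUSP1 (1.49), the growth factors BDNF (1.46) and FGF2 (1.15), the adhesion receptor ICAM1 (1.33) and the telomerase subunit TERT (1.19). PTGS2 and ICAM1 each had 10 spots, which gave a standard error between spots of 0.05 and 0.04 log2. The lower genes included the chemokine CCL2 (-2.20), the ligand WNT10A (-1.82), the secreted proteins WFDC2 (-1.76) and SPP1 (-1.51), the protease KLK6 (-1.46) and the actin-capping protein CAPG (-1.42). HLA-C (-1.22), HLA-B (-1.12) and the pseudogene HLA-J (-1.26) were lower as well, but these genes are near-identical copies, so their probes are uncertain as separate measurements.

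Cell-cell junction genes came next, since claudin-11 and E-cadherin both hold epithelial cells together. Among the 20 claudins measured on both arrays, CLDN11 was the only one at or beyond 2-fold. CLDN22 stood at 0.92 and CLDN2 at 0.88, both at low signals (58 and 112 on the shSNAI1 array), and CLDN6 at -0.48. The claudin list had a median of 0.11, at the 93.9th percentile of the medians of 10000 random lists of the same size and matched mean signal. Taking the mean of each gene's probes gave a median of 0.01 at percentile 71.5. Of 22 other tight-junction components, MARVELD3, a tetraspan tight-junction protein, was 2.50-fold lower by its brightest probe, with a second probe at -0.44, and the list median was -0.08 (percentile 5.52). The polarity genes CRB3 (0.48) and PRKCI (0.39) were the highest of them, and CRB3 lies in a stretch of chromosome 19 where neighbours were higher together.

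None of the 22 adherens-junction and desmosome genes reached 2-fold, and 13 lay below 0. P-cadherin (CDH3) stood at -0.77, CDH1 at -0.76, and the desmosomal plakophilin PKP1 at 0.42. Their median of -0.16 fell at percentile 0.13 of the random lists. CDH1, CDH3 and MARVELD3 lie in stretches of chromosome 16 where neighbouring genes were lower together. Without genes in such stretches the adherens-junction list kept a median of -0.13 at percentile 0.35.

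**Figure D2:**
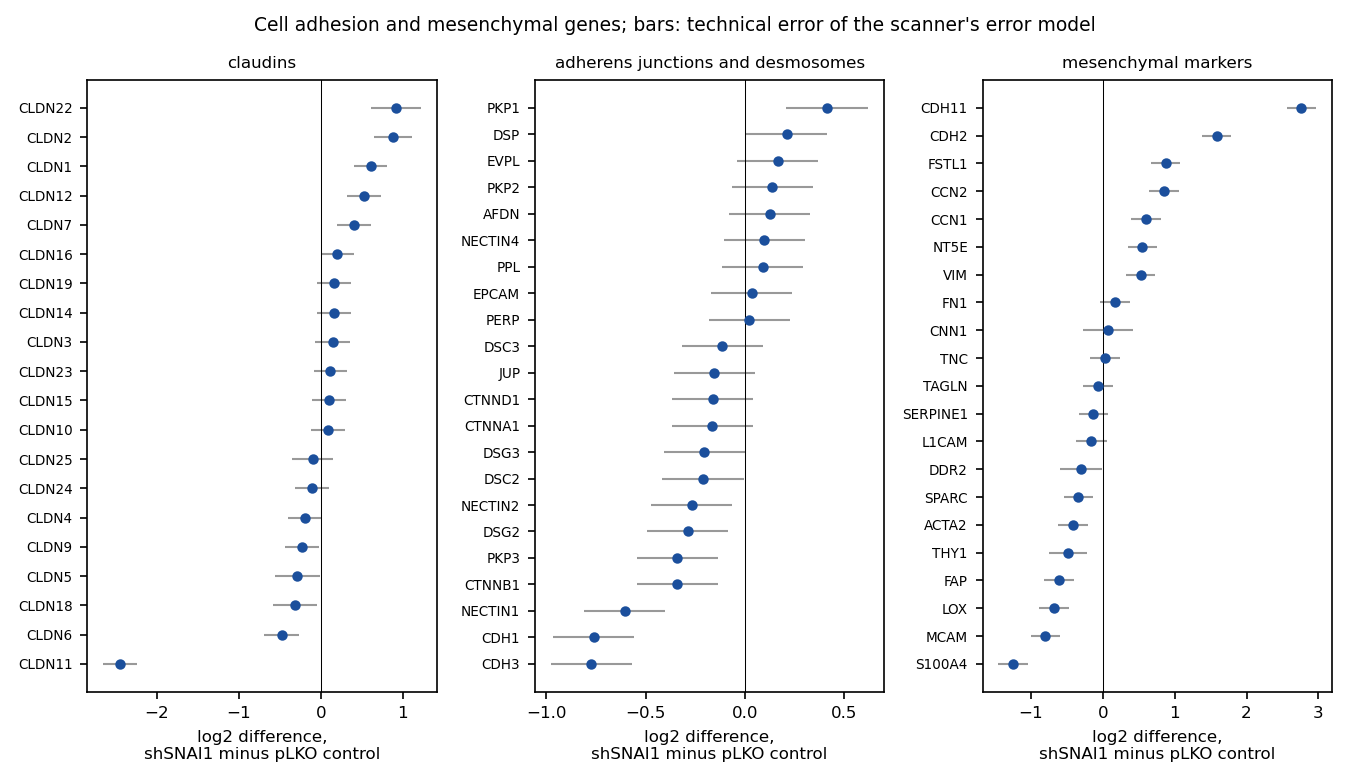
Log2 difference (shSNAI1 minus pLKO control, horizontal axis) of each measured claudin, adherens-junction or desmosome gene and mesenchymal marker, 1 point per gene from 1 array per group, with bars for the technical error of the scanner's error model. CLDN11 sits apart from the other claudins at -2.45, CDH3 and CDH1 are lowest among the junction genes at -0.77 and -0.76, and CDH11 (2.76) and CDH2 (1.58) are highest among the mesenchymal markers.

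Of 23 EMT transcription factors SNAI1 alone was at or beyond 2-fold. The homeobox genes GSC and PRRX1 stood at -0.58 and 0.68, and the epithelial factor ELF3 at 0.49. Their median was -0.02, at percentile 42.6. The 21 mesenchymal markers went both ways. CDH11 (2.76 by its brightest probe, 0.77 by the other) and CDH2 (1.58 by both) were higher, while the calcium-binding protein S100A4 (-1.25) and the adhesion molecule MCAM (-0.80) were lower. The list median was -0.07 at percentile 20.4. Its 9 members with a mean signal of 1000 or more had a median of 0.55 at percentile 99.96, a restriction added after the data were seen.

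Cytokines and chemokines held more 2-fold genes than any other list. Of 29 measured, 7 were at or beyond 2-fold higher and 2 lower, where random lists held 0.54 higher members on average and none of the 10000 held as many. Next to IL24 the higher members were the neutrophil chemokines CXCL1 (1.77, 3.42-fold) and CXCL3 (1.04), the interleukins IL6 (1.37) and IL11 (1.14), and the alarm cytokines IL1A (1.04) and IL1B (1.04). The lower ones were CCL2, at 4.60-fold lower, and CCL20 (-1.56), which lies in a low stretch of chromosome 2. CCL20 was dim, at 56 against 178 in the control. The list median of 0.02 lay at percentile 73.4, with 14 members below 0. Random lists draw genes independently of each other, while members of a list may vary together, which these counts do not allow for. Counts against random lists were not fixed beforehand and were made for each list in both directions. After this and the squamous list, the smallest shares with as many were 1.44% (lower matrix proteases), 3.07% (higher keratins) and 3.97% (higher integrins).

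Squamous differentiation genes held more lower than higher members. Among 31 measured, 4 were at or beyond 2-fold lower, a number that 0.55% of random lists reached, and 1 was higher. The lipocalin LCN2 (-2.20) and the psoriasin S100A7 (-1.75) were lowest, and the calprotectin subunit S100A8 (1.28) and the transglutaminase TGM1 (0.81) highest. LCN2 was dim, at 29 against 144 in the control, while S100A7 had 10 spots. The median of this list was -0.10 at percentile 9.30. Among 22 keratins, the basal keratins KRT14 (2.97-fold) and KRT17 (2.08-fold) were higher at high signal, and KRT23 (-0.90) and KRT6B (-0.80) were lower at low signal. The keratin median was 0.04 (percentile 44.7).

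Matrix proteases and their inhibitors went both ways. The collagenase-activating protease MMP3 was 2.97-fold higher and MMP12 stood at 1.24, while urokinase (PLAU) was 2.78-fold lower and the inhibitor TIMP2 2.42-fold lower. With 3 of its 31 members at or beyond 2-fold lower and 2 higher, the list had a median of 0.09 at percentile 82.0. PLAU lies in a stretch of chromosome 10 where neighbours were lower together. Among 19 integrins ITGB8 (2.30-fold) and ITGA6 (2.03-fold), a laminin-binding subunit, were higher, ITGB6 (-1.41) was lower, and the collagen-binding partner ITGB1 stood at -0.47. ITGB6 was dim, at 57 against 162 in the control. The integrin median was 0.11 (percentile 86.3), and -0.01 (percentile 36.9) when each gene took the mean of its probes. Of 27 collagen and basement-membrane genes only COL4A6 (1.08) reached 2-fold, and its other probe was at 0.00. COL13A1 was 1.99-fold higher, while COL6A1 (-0.86) and COL6A2 (-0.69) were lowest, with a list median of -0.05 (percentile 5.52).

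Interferon-stimulated genes were mostly below 0, 27 of 37, with a median of -0.17 at percentile 1.04. The guanylate-binding protein GBP1 (-1.34) and the oligoadenylate synthetase OAS1 (-1.02) were at or beyond 2-fold lower, IFIT2 stood at -0.89 and MX1 at -0.79, while IFITM1 (0.94) and ISG20 (0.88) were highest. Both GBP1 (109 against 296 in the control) and OAS1 (46 against 100) were dim. In the TGF-beta response list the differentiation inhibitor ID2 was 2.60-fold lower, and both its probes were past 2-fold. BAMBI stood at -0.66, TGFBR1 at 0.69 and ANGPTL4 at 0.55, with a list median of 0.04 over 22 genes (percentile 60.8). Among 24 Notch and Wnt targets NOTCH3 (-1.31) and LEF1 (-1.24) were at or beyond 2-fold lower, SP5 (0.93) and RNF43 (0.58) were highest, and the median was 0.06 (percentile 76.0).

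Sterol synthesis genes were low as a group. The cholesterol and fatty acid list had 21 of 28 members below 0 and a median of -0.16 at percentile 0.01, with no member at or beyond 2-fold. The sterol carrier STARD4 stood at -0.76, MVD at -0.68 and HMGCS1 at -0.48, and the fatty acid elongase ELOVL6 at 0.25. The hypoxia and glycolysis list, with 17 of 28 members above 0, had a median of 0.20 at percentile 96.8, led by NDRG1 (0.95) and ANKRD37 (0.71), with P4HA2 (-0.77) and HK1 (-0.62) lowest. Its median was 0.05 under both quantile normalization (percentile 85.7) and cyclic loess (percentile 89.0).

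In the cell-cycle list of 35 genes the kinase CDK1 was 2.23-fold lower and lies in the low stretch of chromosome 10. MCM6 stood at -0.42, and the mitotic genes KIF20A and AURKA at 0.76 and 0.69. Its median of -0.02 lay at percentile 1.71, a place it lost under quantile normalization (percentile 16.5), cyclic loess (23.1) and normexp background correction (31.3). The 29 stress, ATF4 and p53 targets had a median of 0.17 (percentile 93.6), with MDM2 at 0.79, PSAT1 at 0.63, TXNRD1 at -0.62 and HSPA1A at -0.42. That median was 0.03 under quantile normalization (percentile 70.4) and 0.04 under cyclic loess (percentile 76.4). Of 20 stemness and drug-resistance markers, ITGA6 was again the only one past 2-fold. MYC stood at 0.61, ALDH1A1 at -0.90 and SOX2 at -0.75, with a median of -0.03 (percentile 37.1).

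**Figure D3:**
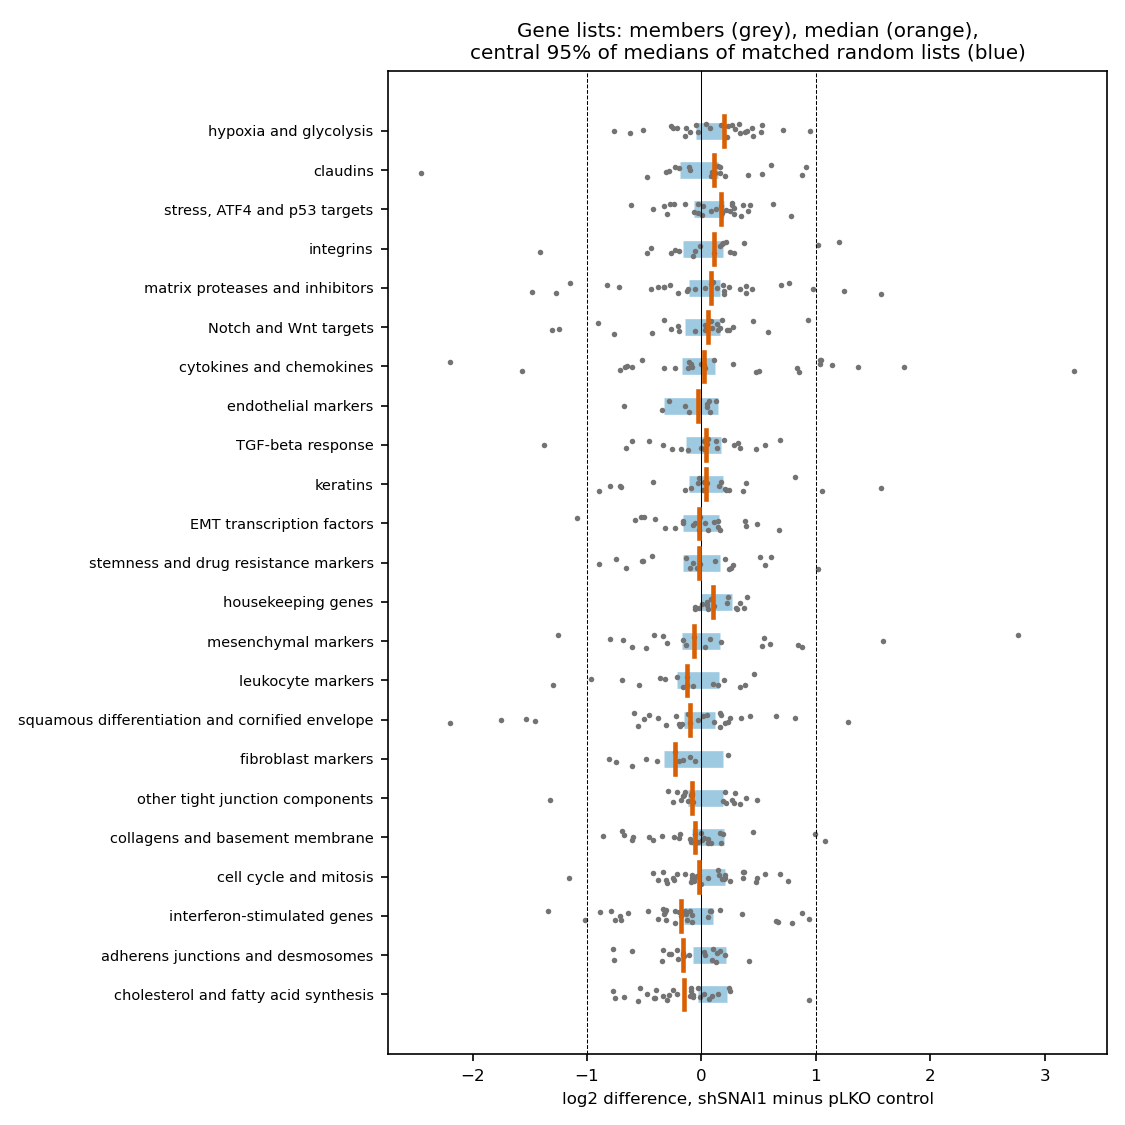
Log2 difference (shSNAI1 minus pLKO control, horizontal axis) of the members of each gene list, 1 grey point per gene from 1 array per group, with the list median in orange and the central 95% of medians of 10000 matched random lists in blue. The cholesterol and fatty acid list (median -0.16), the adherens-junction and desmosome list (-0.16), the interferon-stimulated genes (-0.17) and the cell-cycle list (-0.02) lie below that range.

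Markers of other cell types were compared as well, although a difference between the arrays does not show whether such cells were present. Fibroblast markers had a median of -0.23 (percentile 8.78, 11 genes), with PDGFRA at -0.81, DPT at -0.75 and MFAP5 at 0.23. Leukocyte markers had a median of -0.13 (percentile 14.9, 17 genes). The lysosomal protein CD68, which many cell types express, was 2.46-fold lower, MS4A1 stood at -0.97, CD14 at 0.46 and CD79A at 0.38. CD79A was bright on both arrays, at 6280 for shSNAI1 and 5140 for control, and what its probe measured here was not checked. Endothelial markers had a median of -0.03 (percentile 66.4, 10 genes), from -0.67 for FLT1 and -0.34 for PECAM1 (0.19 by its other probe) to 0.08 for ROBO4 and 0.13 for EMCN. The 16 housekeeping genes spanned -0.06 for HPRT1 to 0.37 for ALAS1 and 0.40 for SDHA, with a median of 0.10 (percentile 28.2) that turned below 0 under quantile and loess normalization. In 12 of 23 lists the median lay so close to 0 that at least 1 scaling alternative changed its sign. Scaling that adds the same constant to all genes leaves a list's place among matched lists as it was.

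By size alone, the most extreme genes were dim ones, and apart from MAGEB2 all had a mean signal under 1000. The 12 lowest were DGKK (-4.97), MAGEB2 (-4.52), CAMK1G (-4.37), SULT1B1 (-4.31), BATF2 (-4.07), NPW (-3.65), LDLRAD3 (-3.64), TUBAL3 (-3.60), IQCF1 (-3.58), GPR179 (-3.42), WTAPP1 (-3.41) and RASGEF1B (-3.35). Among the highest were PPIL6 (4.97), OR1L1 (4.71), OR2T12 (4.39), C1QL4 (4.03), PTPRT (3.98), RGPD4-DT (3.90), GLI2 (3.75), ALPK2 (3.66), TEKT2 (3.44), TRPA1 (3.36) and QRICH2 (3.34). OR1L1 and OR2T12 encode olfactory receptors and MAGEB2 a cancer-testis antigen. All of them rested on single spots. TUBAL3 and GLI2 had another probe of opposite sign, PPIL6 had a second probe at 1.09, QRICH2 had one at 0.27 and IQCF1 had one at -0.45. MAGEB2 had the brightest control signal of the lowest 12, at 5302 against 217 in the shSNAI1 cells.

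Some genes were well above background on 1 array only, 290 on the shSNAI1 array and 231 on the control array, and for these the ratio is a bound. The bound was at least 2-fold for 34 of the former and 72 of the latter. It comes from the brightest probe of a gene and does not allow for spot noise, which was tested only for genes measured on both arrays. The gap-junction gene GJA1 was at least 77.7-fold lower in the shSNAI1 cells, where it was not well above background, against a control signal of 1392. The proprotein convertase PCSK5 was at least 19.99-fold lower by the brightest of its 3 probes, ZNF32 at least 15.2-fold and the olfactory receptor OR4K2 at least 11.1-fold. In the other direction ZNF556 was at least 18.03-fold higher, MANSC4 at least 11.6-fold by the brighter of its 2 probes, HAND2-AS1 at least 11.2-fold and MAGEB6 at least 9.41-fold. Each was not well above background in the control.

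**Figure D4:**
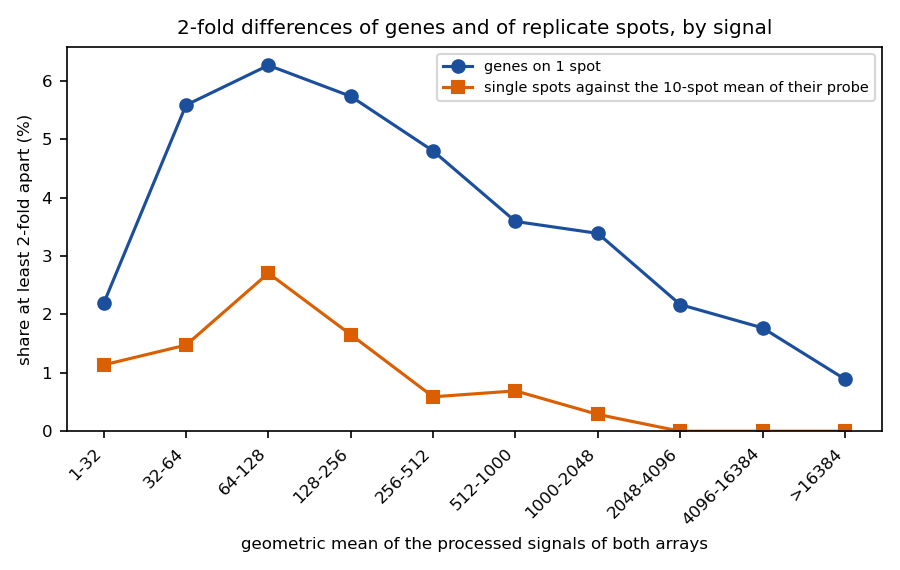
Share (%) of genes on 1 spot that differ at least 2-fold between the arrays (blue), by geometric mean of the processed signals. Orange marks the share of spots whose difference between the arrays lies at least 2-fold from the mean difference of their own 10-spot probe. Between signals of 64 and 128 the shares were 6.27% and 2.71%, and between 2048 and 4096 they were 2.17% and 0.00%.

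Along the chromosomes, 17 stretches stood out in which 25 or more neighbouring genes were shifted together beyond the range of 1000 shuffles of the gene order, a search chosen after the data were seen. They held 969 genes, 4.995% of those placed. Lower stretches lay on chromosome 10 (hg19 45500488 to 70137124 and 72058773 to 81142503), on chromosome 16 (34620339 to 57546437, 67691397 to 70194843 and 70413883 to 75562808), near the end of chromosome 2 (4 pieces between 219528036 and 241896837) and on chromosome 19 (52392549 to 53819218). Higher stretches lay on the short arm of chromosome 19 (5 pieces between 505192 and 19312513), on chromosome 1 (241964700 to 247614390) and on chromosome 4 (123665068 to 140187735). In the lower stretches genes with a mean signal of 1000 or more had a median of 71.6% of their control level, and in the higher ones 147%. These sizes come from genes used to find the stretches. They are not centred on the median of all genes of that signal, which was 0.09 log2. The lower stretches held 45 of the 402 genes at or beyond 2-fold lower, CDK1, PLAU and WNT10A among them, and the higher ones 26 of the 324 placed genes at or beyond 2-fold higher, such as ICAM1 and FGF2.

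**Figure D5:**
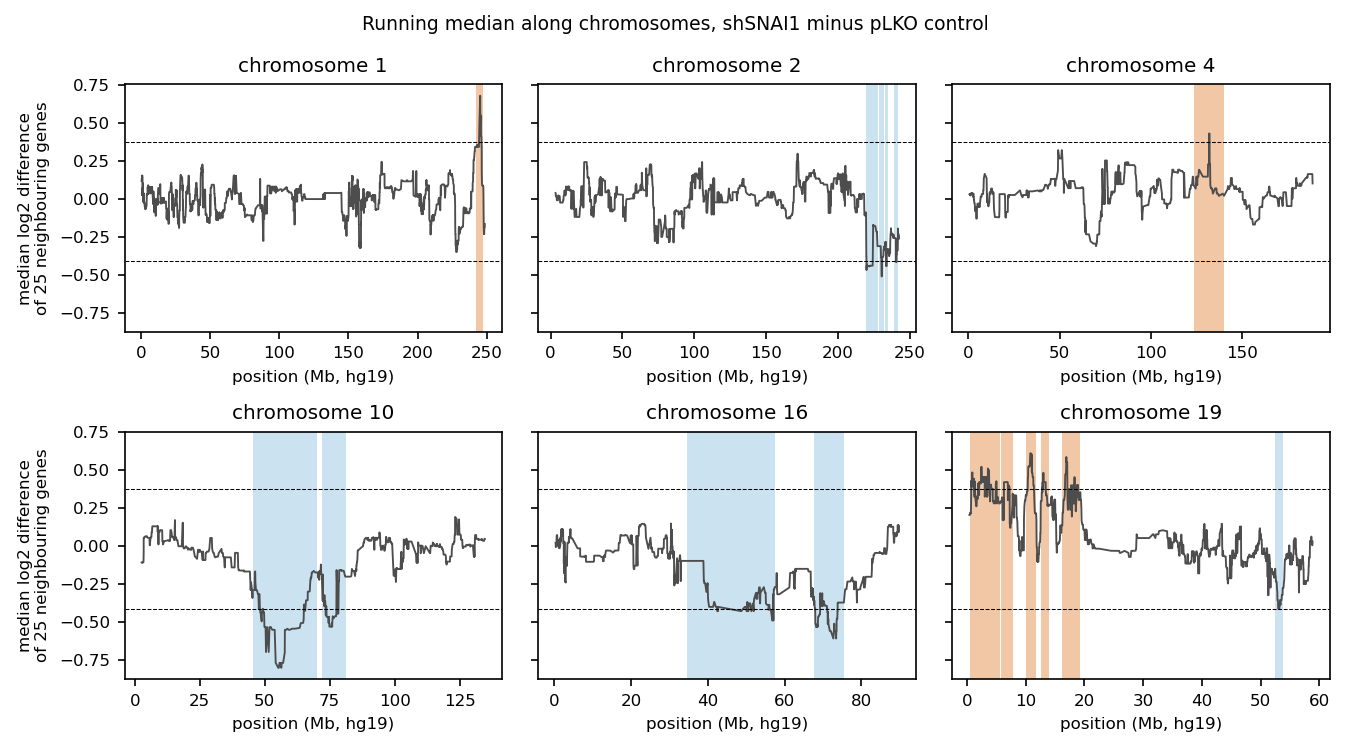
Running median of the log2 difference (shSNAI1 minus pLKO control) of 25 neighbouring genes, centred on the median gene, along the 6 chromosomes with shifted stretches (position in Mb, hg19). Shading marks lower (blue) and higher (orange) stretches, and dashed lines at -0.41 and 0.37 mark the range of the most extreme windows in 1000 shuffles of the gene order.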

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

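The test of single spots, the test of copy number and the support of cytokine probes were chosen after the results were seen, and the tests of probe GC content, array position, chance runs and the place of cytokine genes were set down before theirs. Some probes without a gene name were detected on 1 array only: 741 were well above background on the shSNAI1 array and not on the control array, and 567 the reverse. Of the 14310 unnamed probes measured on both arrays, 189 were at or beyond 2-fold higher and 346 lower.

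The first pattern is the size of the differences of dim genes. Among genes on 1 spot with a mean signal under 1000, 93 were at least 4-fold apart. Noise was taken from probes with 10 spots, as the deviation of each spot's difference between the arrays from its probe's mean difference. At matched signal it would give 68.7% of that number. Spots flagged as outliers were kept in this noise, while genes on flagged spots were left out, so the share may be too high. It also rests on few deviating spots, 1.35% of 591 between signals of 64 and 128. Single-spot noise may therefore account for many of the dim genes past 4-fold, without marking which. How often spots deviate as far as OR1L1 or DGKK was not counted. Among genes with a mean signal of 1000 or more the same noise would give 3.44% of the 175 genes at least 2-fold apart, which argues against it there. At the other thresholds it would give 147 of the 528 dim genes at least 2-fold apart and 2.01 of the 14 bright genes at least 4-fold apart. Differences between cultures and between labelling reactions are not in this noise and stay open for both groups of genes, as does Snail depletion.

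The second pattern is the 17 stretches of neighbouring genes that were higher or lower together. Taking out probe GC content and then mean signal left the median stretch at 93.3% of its shift, and taking out array position left 96.4%. This argues against the GC content of the probes and against array position. The GC content of the transcripts or of the regions was not tested. A chance run of unrelated genes is argued against by the unnamed probes inside the stretches, whose median in the stretch's direction was 0.0665, above the 0.0337 at the upper edge of the central 95% of random sets, although far below 0.39, the median size of the stretches' own shift. When stretches were sought with every other gene, 89.6% of the genes left out with a mean signal of 1000 or more (413 of 461) lay on the stretch's side. Their median in the stretch's direction was 0.47 log2, relative to all left-out genes of that signal. A different DNA copy number of the 2 cell populations would give such a shift. That remains a hypothesis, since no DNA was measured, and regulation of whole regions after Snail depletion could give the same and was not tested.

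The third pattern is the high members of the cytokine and chemokine list. Of the 7 members at or beyond 2-fold higher, 0% lay in higher stretches, which argues against the chromosome shifts. Well-measured probes (bright, on 10 spots or on several probes) stood behind 85.7% of them, which argues against noise of single spots. A response to Snail depletion may remain as a hypothesis, beside a difference between the 2 cultures in density or handling, and 1 array per group leaves both open.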

How the results depend on the processing

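The restriction to a mean signal of 1000 or more and the removal of genes in the shifted stretches were chosen after the data were seen. SNAI1 ranged from -1.14 to -0.98 and CLDN11 from -2.50 to -2.27 over the 9 alternatives fixed beforehand. Of 108 other named genes 3 took both signs. GLI2 (-0.14) and TUBAL3 (0.36) turned under the stricter filter, which left them a probe of opposite sign, and HPRT1 crossed 0 under median scaling. The authors' table values repeat the main values by construction and test nothing. Counts of higher and lower genes were 216 and 208 with normexp, whose offset draws dim ratios toward 0, and 493 and 654 without a filter, which lets in dim genes. The stricter filter, by keeping fewer genes, gave 201 lower, and a mean signal of 1000 or more gave 113 higher and 74 lower. The counts stayed within 1.5 times under the other alternatives.

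For the list percentiles below the cause was not tested. The cell-cycle list stood at 31.3 with normexp, 16.5 with quantile, 23.1 with loess and 2.59 without the stretches. Fibroblast markers stood at 2.01 with normexp, 1.38 with quantile, 1.71 with loess and 2.41 under the stricter filter. The stress list stood at 98.2 with normexp. Hypoxia and glycolysis stood at 99.1 without a filter, 98.7 under the stricter filter and 98.98 without the stretches. At a mean signal of 1000 or more, mesenchymal markers stood at 99.96, cytokines at 100 and stemness markers at 99.87. The other list percentiles kept their side of the central 95%, and endothelial markers gave none at a mean signal of 1000 or more, where no member was left. No paired analysis was possible because each group has 1 array. Signal over background limits the dim genes, and 31 of the 108 named genes gave no value under the stricter filter.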

Other observations

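Apart from GJA1, the genes here were chosen after the data were seen, and no test was run on them. Several genes outside the lists stood far apart at a mean signal of 1000 or more, each on a single spot. The netrin NTN4 stood at 2.14, the annexin ANXA10 at 2.26, the sphingosine-phosphate receptor S1PR4 (in a higher stretch of chromosome 19) at 2.40, the cortactin relative HCLS1 at 2.47 and the bradykinin receptor BDKRB1 at 1.84. The epithelial galectin LGALS7 stood at -2.90, the elongation factor EEF1A2 at -2.70, the collagen-uptake receptor MRC2 at -2.51, the heparin-binding growth factor MDK (midkine) at -1.99 and the guidance ligand SLIT3 at -1.95 by its brightest probe and 0.06 by the other. The cyclin CCND2 was higher at 1.86 and the antiproliferative gene BTG3 lower at -1.79.

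Among single genes, GJB2 (connexin 26) stood at 1.65 on 10 spots, with signals of 544 on the shSNAI1 array and 185 on the control array. GJA1 (connexin 43) was not well above background on the shSNAI1 array and reached 1392 on the control array on a single spot.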
